A study of Tilletiopsis washingtonensis and Meira miltonrushii with 14 samples.

How the data were processed

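RNA-seq libraries of 2 fungal species were analysed, 8 of *Tilletiopsis washingtonensis* and 6 of *Meira miltonrushii*. Per the labels' protocols, cells were precultured in potato dextrose broth for 7 days and moved to Holliday's minimal medium with 1% glucose or 1% Tween40. They were harvested after 3 days at 25 °C, and total RNA went into poly(A)+ libraries made with an Illumina TruSeq mRNA kit. Groups were taken from the labelled growth form within each species. The labels number the replicates of each group without stating that each came from its own culture, so p-values measure the spread between these samples, which may be technical.

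The submitters' processing notes name cutadapt 1.13, TopHat2 2.1.1, HTSeq 0.7.0 and DESeq2 1.20.0, without their roles or order. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The deposited raw tables hold whole-number read counts per protein identifier, with 5 lines for reads that were not assigned and a line of totals. The deposited normalized tables hold a signal that equals the raw count divided by 1 factor per library. Within each library the ratio of raw to normalized count was the same for all genes, with a largest relative deviation of 5e-15. The factors recomputed from the counts by the median-of-ratios method matched these ratios to the decimals compared. Genes with no count in any library, 12 in *T. washingtonensis* and 52 in *M. miltonrushii*, are left out of the deposited normalized tables. All tests of the raw counts started from the deposited counts, and the normalized signal was used only in an alternative test.

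Lines that name no gene were kept out of library sizes and tests. Reads assigned to genes were 81.8% to 85.1% of the listed totals. Reads with no feature were 11.5% to 14.5% in *T. washingtonensis* and 14.3% to 16.2% in *M. miltonrushii*. Multiply aligned reads were 3.24% to 3.96% and 1.55% to 2.01%, and ambiguous reads were at most 0.0635%. Reads shared by near-identical genes may be lost or assigned to one copy, and without a stated strand setting overlapping genes cannot be separated with certainty. Replicate pairs were compared by a chi-square of their counts over genes: the statistic per degree of freedom was 16.9 to 134, so no pair was within sampling noise and every library was kept.

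*T. washingtonensis* identifiers matched locus tags of assembly Tilwa1 for 7004 of 7011 genes. That table gives no product names, and it was used only for locus tags and for which genes are neighbours. No coordinates are given, since the build behind the counts is not named. *M. miltonrushii* identifiers were left as they are. The gene list, product family and between-species list tests fixed in advance need product names and were not run, nor were genes matched between species.

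Differential expression was tested in R 4.3.3 with edgeR 4.0.16, separately in each species: filterByExpr on the growth forms, TMM factors, a robust quasi-likelihood fit on growth form alone, and Benjamini-Hochberg adjustment with a threshold of 0.05. This left 6727 genes in *T. washingtonensis* and 6778 in *M. miltonrushii*; the 284 and 674 genes filtered out held 0.0054% and 0.018% of counts. Log2 fold changes are filamentous over yeast, and CPM values use TMM-scaled library sizes. The SE of a log2 fold change was derived from the test, as its absolute value divided by the square root of the quasi-likelihood F statistic. Principal components and correlations used log2 CPM with a prior count of 2. The rule for named genes, fixed before the data were examined, took in each species the 2 largest increases and the 2 largest decreases with an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the groups' libraries. Its parts that need product names were not used. A floor of 3 counts over the group was used for genes with no count, and intervals of ratios are exact binomial at 95%. PCR reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only. At the totals of these libraries 1 read is worth 0.0330 to 0.137 CPM.

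Measures of single libraries were compared by two-sided exact permutation tests, which cannot reach a p below 0.0286 with 4 against 4 libraries or below 0.1 with 3 against 3. Differences between species in such measures were tested by permuting growth-form labels within each species, 1400 relabellings in all. The abundance groups, the comparison of species at matched size and depth, and the analysis of neighbouring genes were added after the data were seen. Neighbouring genes were taken from the order of protein-coding genes, with 36 sequence ends inferred from the order of positions, and their calls were compared with 10000 shuffles of calls over the 6722 placed genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for these and for plots.

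The differential test was tested on simulated data with 50 genes at each of 4 fold changes. In the *T. washingtonensis* design with 6698 genes it recovered 38% of genes changed 1.5-fold, 92% at 2-fold, 94% at 4-fold and 100% at 8-fold, with 16 false calls. In the *M. miltonrushii* design with 6742 genes it recovered 22%, 78%, 88% and 94%, with 17 false calls. Only these 50 genes per fold change were altered, whereas 61.8% and 66.1% of tested genes were called changed in the data. The rates of recovery and of false calls therefore need not hold for the data. Alternatives were other normalization factors, other filters, DESeq2 1.42.0, limma 3.58.1 (voom, and limma-trend on the deposited normalized counts with pseudocounts of 1 and 10), other thresholds, replicate number as a block, each library left out, and libraries thinned to equal depth.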

Results

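Poly(A)+ RNA was sequenced from 2 dimorphic fungi of the Ustilaginomycotina, the smut fungi and their relatives, each grown as a yeast and as filaments. *Tilletiopsis washingtonensis* was represented by 4 yeast and 4 filamentous libraries, and *Meira miltonrushii* by 3 yeast and 3 filamentous libraries. Yeast growth was on 1% glucose and filamentous growth on 1% Tween40, a polyoxyethylene sorbitan ester of palmitic acid, so every comparison of growth forms was also a comparison of carbon sources. Counts assigned to genes totalled 12.3 M to 30.3 M per library in *T. washingtonensis* and 7.29 M to 17.1 M in *M. miltonrushii*. In *T. washingtonensis* the filamentous library of replicate 4 was the shallowest, at 12.3 M, and the other 3 filamentous libraries held 28.0 M to 30.3 M.

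Growth form was the main axis of variation in both species. The first principal component of log2 CPM, the counts of each library scaled to a common total, took 81.7% of the variance in *T. washingtonensis* and 87.6% in *M. miltonrushii*, and it placed all yeast libraries on one side and all filamentous libraries on the other. Spearman correlations across genes, which are not independent replicates, ran from 0.962 to 0.995 within a growth form and from 0.872 to 0.903 between forms in *T. washingtonensis*. The corresponding ranges in *M. miltonrushii* were 0.961 to 0.992 and 0.784 to 0.819. Replicates were not equally tight: the common biological coefficient of variation was 14.4% in yeast and 19.7% in filamentous *T. washingtonensis*, and 21.2% in yeast and 13.4% in filamentous *M. miltonrushii*.

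**Figure D1:**
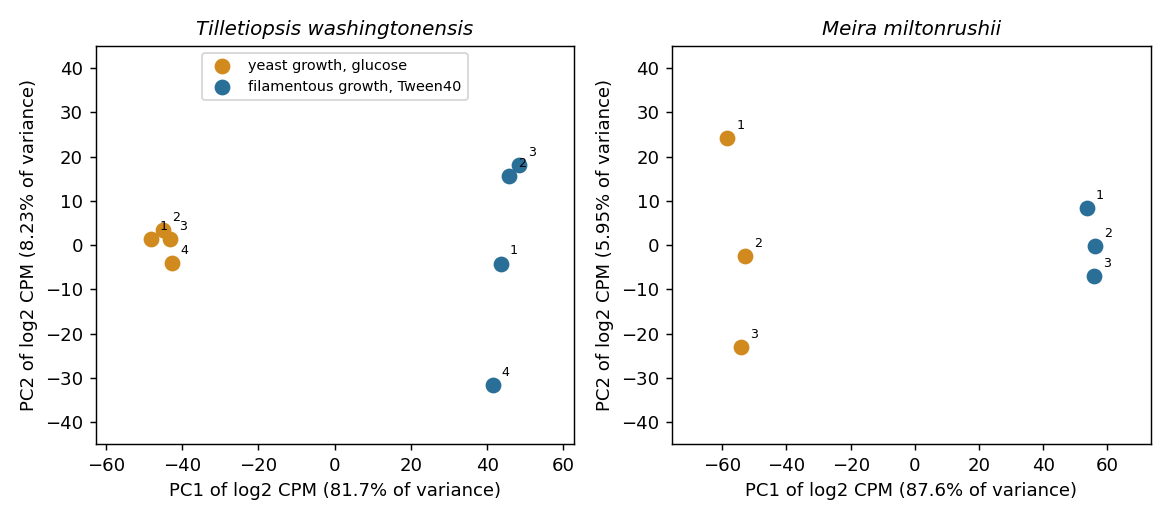
First and second principal components of log2 CPM for each library, with the share of variance on each axis; numbers are replicates, orange is yeast growth and blue is filamentous growth. The first component, with 81.7% and 87.6% of the variance, parts the growth forms in both species, and filamentous replicate 4 of *T. washingtonensis* lies apart from the other filamentous libraries on the second.

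The first comparison asked which *T. washingtonensis* transcripts differ between filamentous and yeast growth. Transcripts of 2091 genes were higher and those of 2065 genes were lower in filamentous growth, together 61.8% of the 6727 genes tested. The genes that rose supplied 44.4% ± 1.99 of all gene counts in filamentous libraries and 21.4% ± 0.625 in yeast libraries (SD, n = 4). The genes that fell supplied 25.1% ± 1.30 and 48.6% ± 0.821. These sets were chosen for their change, so the shares describe its size and are not a further test of it. At least a 2-fold change was found for 817 genes that rose and 825 that fell, and at least a 4-fold change for 263 and 225. The median change was 0.83 on the log2 scale among genes that rose and -0.85 among those that fell.

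In *T. washingtonensis* called genes with a mean of at least 10 CPM and no overlap between the groups' libraries, the largest increases were those of FA09DRAFT_328530 and FA09DRAFT_151432. FA09DRAFT_328530 stood at 624 ± 146 CPM in filamentous and 5.14 ± 0.985 CPM in yeast libraries (SD, n = 4), a log2 fold change of 6.93 (SE 0.24, edgeR adjusted p = 4.2e-09). FA09DRAFT_151432 stood at 48.6 ± 22.5 and 0.749 ± 0.319 CPM, a log2 fold change of 6.04 (SE 0.44, edgeR adjusted p = 7.4e-07). The largest decreases under the same limits were those of FA09DRAFT_292543 and FA09DRAFT_315825. FA09DRAFT_292543 was an abundant yeast transcript, at 1770 ± 535 CPM, and was at 5.34 ± 1.68 CPM in filamentous libraries, a log2 fold change of -8.35 (SE 0.34, edgeR adjusted p = 9.39e-09). FA09DRAFT_315825 went from 20.9 ± 2.02 CPM in yeast to 0.135 ± 0.101 CPM in filamentous libraries, where the 4 libraries together held 14 counts, with a log2 fold change of -7.15 (SE 0.33, edgeR adjusted p = 2.04e-08). The reference table pairs these identifiers with locus tags only, and no product is named for them here.

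In *T. washingtonensis* calls were made with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, and 3629 of the 4156 called genes (87.3%) had filamentous and yeast libraries that did not overlap in CPM. Over all genes tested, 55.6% had groups that did not overlap, where chance gives 2.86%. With upper-quartile factors 2452 genes were higher and 1766 lower, or 58.1% higher against 50.3% with TMM factors. The number of genes that rose at least 4-fold was carried in part by rare transcripts: it was 146 among genes with a mean of at least 10 CPM and with limma-trend on the deposited normalized counts it was 304 with a pseudocount of 1 and 171 with a pseudocount of 10.

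**Figure D2:**
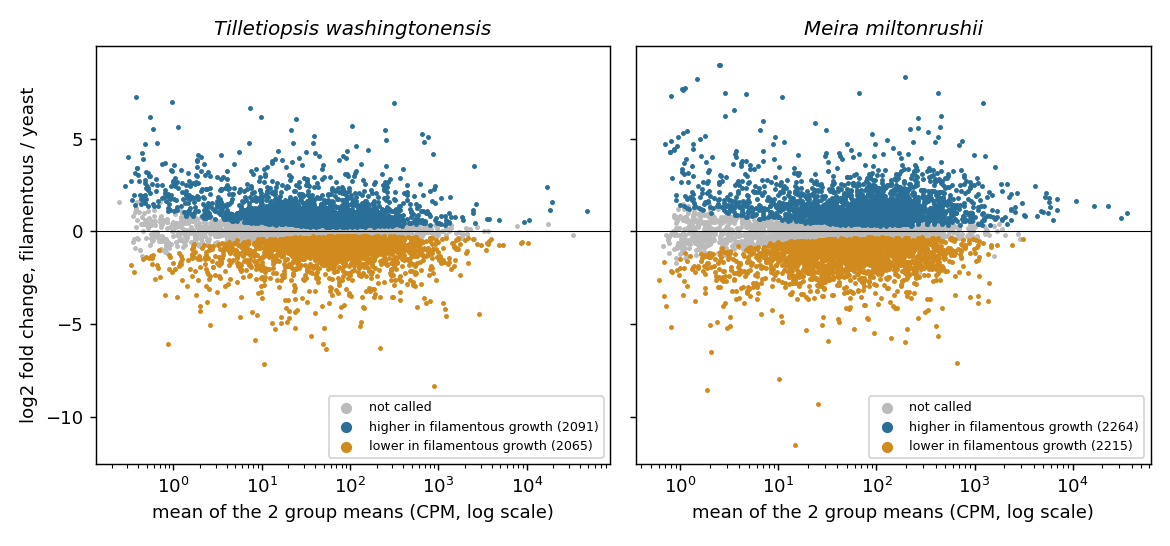
Log2 fold change between filamentous and yeast growth against mean abundance in CPM (log axis), 1 point per tested gene. Genes called higher in filamentous growth are blue (2091 and 2264), genes called lower are orange (2065 and 2215) and the rest are grey; the fitted value of a gene with no count in one group depends on a prior count and is no measured fold.

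The second comparison asked the same of *M. miltonrushii*. Transcripts of 2264 genes were higher and those of 2215 genes were lower in filamentous growth, together 66.1% of the 6778 genes tested. The genes that rose supplied 68.6% ± 0.580 of gene counts in filamentous libraries and 37.3% ± 0.835 in yeast libraries (SD, n = 3), and the genes that fell supplied 12.8% ± 0.380 and 38.6% ± 1.196. At least a 2-fold change was found for 1286 genes that rose and 1322 that fell, and at least a 4-fold change for 414 and 398. The median change was 1.11 on the log2 scale among genes that rose and -1.15 among those that fell.

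The files do not pair *M. miltonrushii* protein identifiers with gene names. Under the same limits on abundance and overlap, the largest increases were those of proteins 160091 and 81747. Protein 160091 stood at 392 ± 15.3 CPM in filamentous and 1.23 ± 0.219 CPM in yeast libraries (SD, n = 3), a log2 fold change of 8.29 (SE 0.19, edgeR adjusted p = 9.31e-10). Protein 81747 stood at 839 ± 103 and 4.76 ± 0.377 CPM, a log2 fold change of 7.46 (SE 0.19, edgeR adjusted p = 1.22e-09). The largest decreases under these limits were those of proteins 161865 and 161864. Protein 161865 had 0 counts in the 3 filamentous libraries and 1322 counts in the 3 yeast libraries, where it stood at 29.6 ± 5.59 CPM. Set against a floor of 3 counts over the filamentous group, it was at least 273-fold lower in filamentous growth (edgeR adjusted p = 4.61e-07). Protein 161864 had 2 counts in filamentous and 2329 in yeast libraries, a ratio of 722 with a 95% exact binomial interval of 200 to 5970, which covers counting error only (edgeR adjusted p = 1.67e-08).

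In *M. miltonrushii*, 98.0% of the called genes had filamentous and yeast libraries that did not overlap in CPM. Over all genes tested the share was 71.2%, where chance gives 10%. The balance between directions depended on the scaling. With TMM factors 50.5% of the called genes were higher in filamentous growth, and with library size alone 1483 were higher and 3123 lower, or 32.2% higher, as that scaling shifted the median log2 fold change by -0.39. At least a 2-fold change was then found for 819 genes that rose and 1963 that fell, and at least a 4-fold change for 279 and 666.

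The most abundant genes took a larger share of counts in filamentous libraries of both species. The 10 most abundant genes of each library took 23.9% ± 1.88 of gene counts in filamentous and 15.2% ± 0.307 in yeast *T. washingtonensis* (SD, n = 4), and the exact permutation p was 0.0286, the smallest that 4 against 4 libraries allow. In *M. miltonrushii* they took 18.1% ± 0.933 and 10.9% ± 0.966 (SD, n = 3), with an exact permutation p of 0.1, the smallest that 3 against 3 allow. The 100 most abundant genes took 42.5% ± 2.89 and 36.3% ± 1.07 in *T. washingtonensis* and 38.3% ± 1.127 and 27.3% ± 1.98 in *M. miltonrushii*, with the same exact p-values. All these tests were two-sided and belonged to a family of 20, in which their adjusted p was 0.143, so none passed the correction. Every filamentous library was above every yeast library of its species for both shares. The number of top-ranked genes that together hold 50% of counts was 203 ± 54.9 in filamentous and 271 ± 22.9 in yeast *T. washingtonensis* (SD, n = 4, exact permutation p = 0.114, adjusted p = 0.152). The forms overlapped on it, as filamentous replicate 4 needed 283 genes and the yeast libraries 256 to 305. In *M. miltonrushii* it was 249.7 ± 16.04 and 468 ± 53.7 (SD, n = 3, exact permutation p = 0.1).

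The identity of the most abundant transcripts changed as well. Of the 100 genes with the highest mean abundance in each form, 66 were shared between forms in *T. washingtonensis*. Pairs of single libraries of the same form shared 82 to 96 of their own 100 most abundant genes. Form means and single libraries differ in noise, so these overlaps are not like measures. In *M. miltonrushii* 55 were shared between forms, and pairs of single libraries of the same form shared 79 to 91. The most abundant filamentous transcript of *T. washingtonensis*, FA09DRAFT_321118, took 6.52% ± 0.475 of gene counts there and 3.02% ± 0.112 in yeast libraries (SD, n = 4), a log2 fold change of 1.11 (SE 0.16, edgeR adjusted p = 8.65e-05). The most abundant yeast transcript, FA09DRAFT_330858, took 3.59% ± 0.130 in yeast and 3.09% ± 0.212 in filamentous libraries, and its change was not called (log2 fold change -0.22, edgeR adjusted p = 0.236). In *M. miltonrushii* 1 gene was the most abundant in both forms, at 4.17% ± 0.172 in filamentous and 2.76% ± 0.152 in yeast libraries (SD, n = 3).

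**Figure D3:**
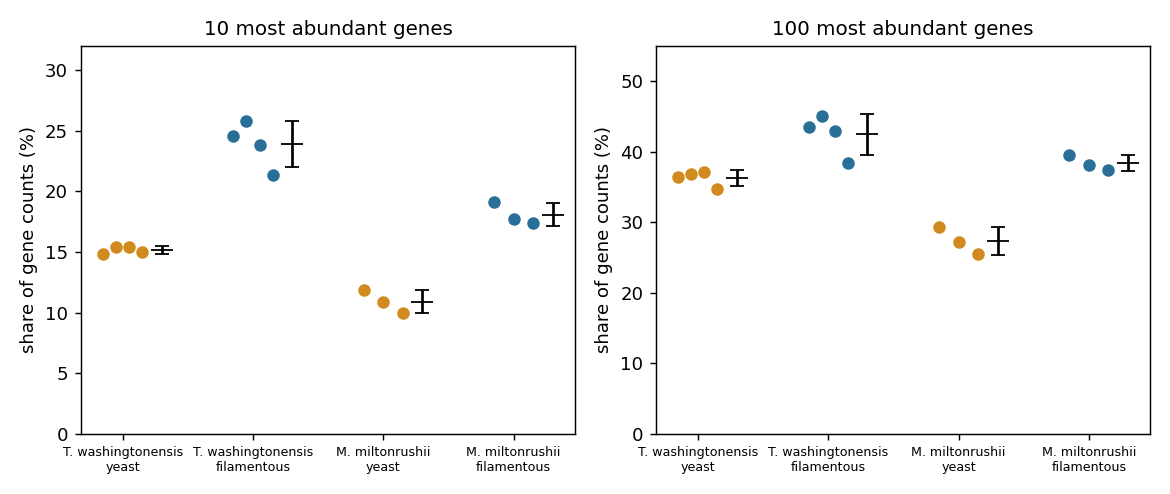
Share of gene counts (%) taken by the 10 and the 100 most abundant genes of each library; points are libraries, and the bar beside them gives the mean and SD of the group. Filamentous libraries lie above yeast libraries in both species, with means of 23.9% and 15.2% in *T. washingtonensis* and 18.1% and 10.9% in *M. miltonrushii* for the 10 most abundant genes.

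The third comparison set the 2 species side by side. Log2 fold changes spread more widely in *M. miltonrushii*: the SD of the log2 fold changes over all tested genes was 1.40 there and 1.12 in *T. washingtonensis*, and 38.5% and 24.4% of tested genes changed at least 2-fold. The values also differed when *T. washingtonensis* was reduced to 3 libraries per form and all libraries were thinned to 7.29 M counts. Over the 16 such subsets the SD was 1.07 to 1.126 and 22.6% to 25.1% of genes changed at least 2-fold, against an SD of 1.39 and 38.1% in thinned *M. miltonrushii*. No test of this difference between species was run, and the genes of the 2 species were not matched to each other here.

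The balance of genes that rose and fell varied with transcript abundance. Among the most abundant of 4 equal groups of genes ranked by mean CPM, 423 *T. washingtonensis* genes rose and 750 fell, while in *M. miltonrushii* 740 rose and 542 fell. With library size alone the *M. miltonrushii* split was 544 and 760. Library scaling largely cancels in the median log2 CPM of this group minus that of all tested genes. It does not cancel fully, as the groups were ranked by TMM-scaled CPM and a small constant was added before the log. This measure changed by -0.19 from yeast to filamentous libraries of *T. washingtonensis* (exact permutation p = 0.0571) and by 0.16 in *M. miltonrushii* (exact permutation p = 0.1). The difference between species was 0.35 (two-sided exact permutation of growth-form labels within each species, p = 0.00286, adjusted p = 0.0124 over 13 measures). This permutation takes as its null no response in either species, so its p speaks against that null and not for unequal responses alone.

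Changed genes of *T. washingtonensis* lay next to one another more often than in shuffled gene orders. Of 6460 pairs of neighbouring tested genes on assembly Tilwa1, 1679 were called in the same direction, against a mean of 1232.8 over 10000 shuffles of genes (one-sided permutation p = 0.0001, the smallest they can give). Among genes changed at least 4-fold, 76 neighbouring pairs moved in the same direction against a mean of 17.1, and 11 moved in opposite directions. The number of such same-direction pairs was 34 among genes with a mean of at least 10 CPM, and with limma-trend on the deposited normalized counts it was 87 with a pseudocount of 1 and 49 with a pseudocount of 10. Shuffles were not run for these settings, whose numbers of changed genes differ, so the mean of 17.1 is not their comparison. The following genes were chosen after their values were seen. The longest stretch of consecutive genes that rose at least 4-fold ran over 6 genes, from FA09DRAFT_192352 to FA09DRAFT_192689, with log2 fold changes of 2.23 to 2.92. A stretch of 5 genes from FA09DRAFT_75309 to FA09DRAFT_331036 rose by 2.1 to 5.48, and within it FA09DRAFT_331033 stood at 488 ± 264 CPM in filamentous and 10.9 ± 5.98 CPM in yeast libraries (SD, n = 4). A stretch of 3 genes from FA09DRAFT_175300 to FA09DRAFT_332830 had log2 fold changes between -3.53 and -5.66. Its middle gene FA09DRAFT_175412 stood at 1481 ± 202 CPM in yeast and 109 ± 13.98 CPM in filamentous libraries. The smallest gap between neighbours was -98, -309 and -9 bp in the stretches of 6, 5 and 3 genes, so each held overlapping genes. Reads shared between such genes were not tested for these stretches.

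**Figure D4:**
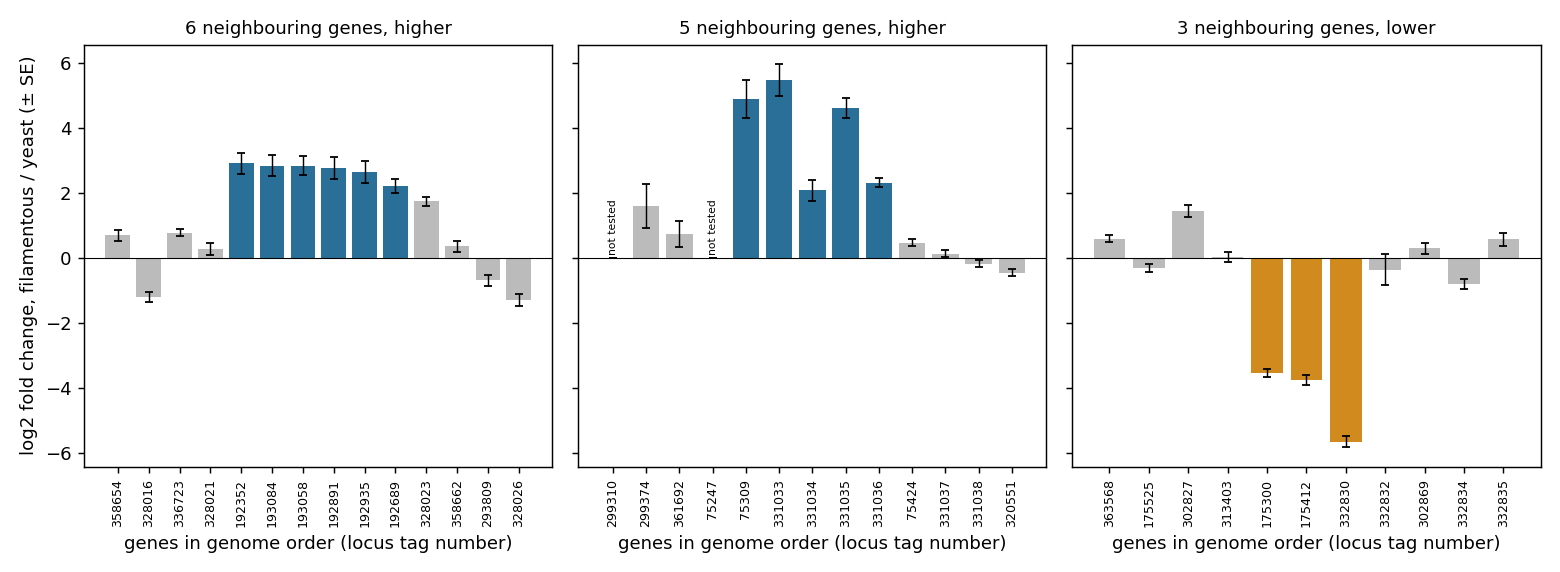
Log2 fold change between filamentous and yeast growth (bars, with the SE) for neighbouring *T. washingtonensis* genes in genome order, with up to 4 flanking genes on each side. Coloured bars are the stretches of 6, 5 and 3 genes that changed at least 4-fold in one direction, grey bars are flanking genes, and genes that did not pass the count filter carry no bar.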

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

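The tests of abundance groups between species were chosen only after the counts of changed genes per abundance group were seen. Within groups of 4 libraries, 32 sets of values were searched for a library far from the others, 3 were found, and chance gives about 1 in 20, or 1.6. All 3 concerned replicate 4 of *T. washingtonensis*, and without its filamentous library 2194 genes were higher and 2165 lower in filamentous growth. That library held 12.32 M gene counts and 6907 detected genes, each far below the other filamentous libraries. The yeast library of replicate 4 had a TMM factor of 1.069, far above the 0.971 to 0.974 of the other yeast libraries.

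Filamentous replicate 4 of *T. washingtonensis* also stood apart in its profile, with a root mean square log2 distance of 0.443 to the mean of the other filamentous libraries, against 0.209, 0.265 and 0.322 for the others. Lower sequencing depth would remove this once all were thinned to its depth, but the ratio of its distance to the mean of the others was 1.637 over 20 thinnings (range 1.627 to 1.642) and 1.671 before. RNA from yeast-form cells like those on glucose would raise yeast transcripts. Among genes with at least 20 CPM in yeast libraries, 26 were at least 16-fold lower in the other filamentous libraries. These genes, which were not required to be silent there, gave a share of -0.52% (95% bootstrap interval -1.02 to 0.06). By contrast, the 22 genes with the reverse pattern would need 18.7% (5.34 to 54.86). What stays open is a difference in culture or library preparation, which may be shared with yeast replicate 4. That library was the farthest yeast library (0.302 against 0.192, 0.158 and 0.242). Its deviations correlated with those of filamentous replicate 4 at 0.148, but replicates 1, 2 and 3 gave 0.159, 0.176 and -0.022 between forms. Its title and label numbers match those of filamentous replicate 4, and such matches also hold for the other replicates. Both libraries of replicate 4 had the highest TMM factor of their group (1.069 and 1.167). No label says what a shared number stands for, and apart from the mixture with yeast-form cells no biological explanation was tested.

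The changes of the 4 abundance groups were compared between the species. From the least to the most abundant group, the change of the group's median relative to all tested genes in *M. miltonrushii* minus that in *T. washingtonensis* was -0.21, -0.156, 0.185 and 0.349 on the log2 scale. The adjusted exact permutation p-values were 0.0419, 0.0124, 0.0124 and 0.0124 over 13 measures. The permutation takes as its null no response in either species, so a small p does not by itself show unequal responses, and the 4 groups share one ranking and are not independent. For the least abundant group the exact permutation p within each species was 0.0857 and 0.2, and the libraries of the forms overlapped in both. In the second group every filamentous library lay above every yeast library in *T. washingtonensis*, by 0.076 on average, and below in *M. miltonrushii*, with a change of -0.08.

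Among reads outside the gene counts, those with no feature made up 15.53% of the listed total in filamentous and 14.45% in yeast *M. miltonrushii*, and multiply aligned reads made up 1.944% and 1.663%. In both, every filamentous library was above every yeast library. The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow, and the adjusted p was 0.143 over 20 tests. The means of *T. washingtonensis* were higher in filamentous libraries as well, but its forms overlapped. Reads with no feature were 13.36% and 12.04% there (exact permutation p = 0.0571), and multiply aligned reads 3.646% and 3.432% (exact permutation p = 0.257).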

How the results depend on the processing

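The settings with thinned libraries, 3 libraries per form, neighbouring pairs and the species difference without single libraries were chosen only after the results were seen. The 8 genes named by the rule kept their direction and their call in every setting run (88 alternative values in *T. washingtonensis* and 80 in *M. miltonrushii*). They were chosen for the largest changes without overlap between groups, so this says little about other called genes. Leaving out 1 library gave 1876 to 2194 genes higher and 1874 to 2165 lower in *T. washingtonensis*, and 2014 to 2298 and 2021 to 2308 in *M. miltonrushii*. Requiring at least a 2-fold change left 817 and 825 genes in *T. washingtonensis* and 1286 and 1322 in *M. miltonrushii*, and glmTreat against 2-fold left 459 and 488, and 817 and 846. These drops follow from the stricter thresholds. Library size alone gave 1483 genes higher in *M. miltonrushii*, since it shifts the median by -0.39. Upper-quartile factors shifted it by 0.10 in *T. washingtonensis* and -0.14 in *M. miltonrushii*. DESeq2 gave 2244 and 2133 genes in *T. washingtonensis* and 2289 and 2279 in *M. miltonrushii*. Replicate number as a block gave 2172 and 2143, and 2335 and 2250. These are the numbers of the sample titles. The library labels carry other numbers, which still match between forms for all 4 title replicates of *T. washingtonensis* but only for title replicate 2 of *M. miltonrushii*. Deviations of libraries with the same title number correlated at 0.159, 0.176, -0.022 and 0.148 in *T. washingtonensis*, where each library but those of replicate 3 correlated best with its own number, and at 0.23, -0.09 and 0.182 in *M. miltonrushii*. The numbers were not taken to pair samples because the titles renumber the library labels. Not all of the correlations were over 0.1, and they are only a hint from the data. The difference between species in the most abundant group was 0.305 to 0.398 without any 1 library. The list, product family and between-species list alternatives were not run. With every library thinned to 7.29 M counts, 1960 and 1935 genes were called in *T. washingtonensis* and 2241 and 2151 in *M. miltonrushii*.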

Other observations

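The analysis of neighbouring genes was chosen only after the data were seen; the predictions for its technical explanations were written before their tests were run. Coordinated change in *T. washingtonensis* was largest between adjacent genes. Across 6460 pairs of adjacent genes, which are not independent replicates, the Spearman correlation of log2 fold changes was 0.234, and it was 0.089, 0.032, 0.042, 0.03 and 0.01 for genes 2, 3, 5, 10 and 20 apart. The upper limit of the central range of 1000 shuffles was 0.023 to 0.025, so only the value at 20 apart lay within it. There were 7 stretches of at least 3 consecutive genes that rose at least 4-fold, against a mean of 0.38 and a maximum of 3 in 1000 shuffles. There were 3 that fell at least 4-fold, against a mean of 0.21 and a maximum of 3. Several of these held genes with a mean under 10 CPM, and stretches were not counted without such genes. Mean CPM was 0.39 to 3.8 from FA09DRAFT_329252 to FA09DRAFT_250297. It was 1.26 to 3.5 from FA09DRAFT_341220 to FA09DRAFT_362939. In the stretches of 6, 5 and 3 genes described above the lowest mean CPM was 21.51, 72.45 and 36.52. At the other limits, stretches of at least 5 called genes numbered 35 that rose and 35 that fell, against shuffle maxima of 23 and 22. Those of at least 4 genes changed at least 2-fold numbered 16 and 12, against maxima of 5 and 6. The longest single stretch was set against the longest of either direction in the shuffles. It was 9 called genes that rose and 10 that fell against 14, so it was no longer. At least 2-fold it was 7 and 5 against 8, again no longer. For genes that fell at least 4-fold it was 3 against 5, and for genes that rose at least 4-fold 6 against 5.

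Same-direction change of adjacent genes may reflect shared regulation of gene neighbourhoods, a hypothesis that was not tested. The same-direction change itself was found and compared with shuffles on the same data. Reads shared between close or overlapping genes would confine it to close pairs, but pairs at least 1000 bp apart held 314 same-direction calls, 1.363 times the shuffle mean. Similar expression levels of neighbours would also produce it, but shuffling only within deciles of mean CPM still left 1.355 times the shuffle mean. Tandem copies that share reads were not tested, as no sequences were used here, and strand is not used, so antisense reads also stay open.

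For the counts of changed genes, only 1 of the 35 splits of the 8 *T. washingtonensis* libraries into 4 and 4 gave as many genes as the growth forms, the growth forms themselves (4156). That share is under 0.05 and is the smallest that 35 splits can give. It speaks only against an arbitrary division of these libraries, as the labels do not state that each came from its own culture. The highest of the other splits called 0 genes with edgeR, the only tool run on the splits, and at most 966 genes at an unadjusted p under 0.05. In *M. miltonrushii* 1 of the 10 splits gave as many, the growth forms with 4479 genes, and the highest other called 0 genes with edgeR and at most 72 at an unadjusted p under 0.05. The 10 splits are too few for a share under 0.05. Other splits mix the growth forms within groups and so carry their difference as spread.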
